A study of Mus musculus with 2 samples.

How the data were processed

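RNA sequencing of whole uterus was carried out on gestational day 4 in mice of 2 genotypes that the labels call f/f and d/d for Mettl14. The data hold 1 library per genotype, so 2 libraries in all. Per the labels' protocols, females were mated with fertile males, the day of the vaginal plug was counted as the start of gestation, total RNA was extracted with TRIzol and libraries were made with the TruSeq RNA kit. The strandedness of the library, the read length and the annotation release are not given in the sources used here, nor is it stated whether each library came from 1 animal or a pool.

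The deposited values are FPKM, fragments per kilobase of gene model scaled to the mapped fragments of the library, made by the authors. The submitters' processing notes name HISAT2 version 2.2.1, Cufflinks version 2.2.1 and the mouse build mm10. Each deposited file gives a gene symbol, an Ensembl gene ID and 1 FPKM value per gene, with no read counts and no confidence limits. Both files list the same 55483 rows. FPKM depends on an estimated effective transcript length and on how Cufflinks shares fragments between overlapping transcripts and gene copies, so values of gene models with very short transcripts, of pseudogenes and of near-identical paralogs are uncertain. The FPKM values summed to 1281240 in the f/f library and to 1285317 in the d/d library.

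Depth was estimated from the smallest steps of the values. Among genes with 1 annotated transcript of at least 2000 nt, FPKM times length falls near whole multiples of the value of 1 fragment. The best-fitting depth was 17700000 fragments for f/f, where 74.5% of 803 low values lay within 0.1 of a whole number. For d/d it was 20650000 fragments, where 69.6% of 835 low values did. At that depth 1 FPKM over a 2 kb transcript stands for about 35.4 fragments in f/f and 41.3 in d/d. The fit used full annotated transcript length in place of the effective length behind FPKM, which is shorter, so these depths are approximate and tend to be too low. They served to describe precision and entered no comparison.

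Rows that share a symbol, 120 of them beyond the first of each symbol, were summed to 55363 genes. For each gene the log2 ratio of d/d over f/f was computed on (FPKM + 1). This pseudocount understates the change of genes near or below 1 FPKM. Genes with 1 FPKM or more in at least one library were counted, which left 16263. With 1 library per genotype there is no spread between animals, hence no test, standard error or p-value. A gene was counted as higher or lower when its log2 ratio was at least 1 in size, which is 2-fold on that scale. The words higher and lower compare these libraries and not the genotypes.

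Before the data were examined, 40 gene lists were fixed from general knowledge of the uterus, hormone response, cell types and stress pathways. They also covered tissues that could be carried over, signs of RNA handling and reference genes. Symbols were matched to the files directly or through the gene IDs of GENCODE M21. The symbols Kiaa1429, Irg1, Clca3, Spink3, Rigi, Hbb-b1, Hbb-b2 and Rn45s had no match and dropped out. Of these, Kiaa1429, Irg1, Spink3 and Rigi are other names of Virma, Acod1, Spink1 and Ddx58, which the same lists hold and which were measured. Some genes sit in more than 1 list. A list's median log2 ratio over its measured genes was placed among the medians of 10000 random lists of the same size, drawn without repeats from the same 20 bins of mean expression. A list below the 2.5th or above the percentile 97.5 is described as standing apart. This describes the libraries and is not a test between genotypes, since genes within a list are not independent. About 1.95 of the 39 lists with a percentile would stand apart by chance if genes were independent.

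The genes named were chosen by a rule fixed before the data were examined. They were Mettl14 and the other m6A genes, then the 12 largest and 12 smallest log2 ratios among genes at 5 FPKM or more in at least one library, without gene models, clone names, small RNAs and immunoglobulin or T cell receptor segments. From each list followed up to 6 measured genes with the largest ratios past the 2-fold rule or, where none passed, up to 3 with the highest mean FPKM. Genes named outside this rule are said to be so, and some genes within it are not reported here.

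Positions, gene types and transcript lengths come from GENCODE M21 on GRCm38, the assembly also called mm10, which held 55137 of the 55483 gene IDs. Its release was not matched to the authors' annotation. The scripts were tested on simulated data of the f/f and d/d comparison with 16263 genes, where log2 ratios of unchanged genes had an SD of 0.3. All 200 genes planted at 4-fold were recovered (100%), a list of 20 genes shifted by 1 on the log2 scale stood apart, and 3.25% of 400 random lists with no shift did. Planted genes had a mean of 5 FPKM or more, the noise held no counting error and genes were independent. Real log2 ratios spread more widely, with quartiles of -0.41 and 0.41. The simulation therefore checks the scripts and gives no error rate for the real libraries. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

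Alternatives fixed in advance were a pseudocount of 0.1, rescaling to TPM, centring on the median gene, a total without the 50 most abundant genes, the highest row per symbol, no filter or a filter of 5 FPKM, 1.5-fold and 4-fold rules, random lists not matched on expression, and the mean in place of the median. Chosen after seeing the data were protein-coding genes alone, the removal of genes with an annotated transcript under 250 nt, a correction for GC content, and the removal of list genes shared with another list or of the Sprr2 and Padi families.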

Results

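Uterine gene expression was compared between a Mettl14 f/f and a Mettl14 d/d mouse library on gestational day 4, the day on which the mouse uterus prepares for embryo attachment. Mettl14 encodes the RNA-binding partner of Mettl3 in the complex that writes N6-methyladenosine (m6A) on RNA. In the usual notation f/f stands for floxed and d/d for deleted alleles. The f/f library is the control, and the question was which transcripts differ in the d/d uterus. There was 1 library per genotype, so no value below has a replicate error, and each difference is one between these libraries. Estimated depth was 17700000 fragments for f/f and 20650000 for d/d. In f/f 15417 genes reached 1 FPKM, and in d/d 15216 did. FPKM correlated across the 14370 genes at 1 or more in both libraries with a Spearman rho of 0.89, a value across genes, which are not independent replicates.

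Mettl14 itself was 13.6 FPKM in the f/f library and 3.21 FPKM in the d/d library, a 4.25-fold lower level. On the log2(FPKM + 1) scale this was a ratio of -1.80, at or below which lay 397 of the 16263 genes. The gene (ENSMUSG00000028114) is annotated on the minus strand of chromosome 3 from 123368297 to 123386108. Gene-level FPKM does not show which exons the remaining fragments came from. Of the 19 measured m6A writers, erasers and readers, Mettl14 was the single gene lower by at least 2-fold. Its partner Mettl3 was 19.7 FPKM in f/f and 14.7 in d/d. The erasers Fto and Alkbh5 had log2 ratios of -0.33 and 0.10. Higher by at least 2-fold were the readers Ythdf2, at 23.3 FPKM in f/f and 64.2 in d/d, and Ythdf1, at 33.8 and 71.0, as well as the writer-complex gene Rbm15, at 5.51 and 13.6. The median of the list was 0.32, at percentile 97.3 of matched random lists and so within their range. It passed that range with a filter of 5 FPKM (0.42) and after a correction for GC content (0.36).

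Large differences separated the libraries. Of 16263 genes, 1652 were at least 2-fold higher in d/d and 1346 at least 2-fold lower, together 18.4%, and 2391 of these 2998 genes are protein-coding. The middle of the distribution lay near 0, with a median log2 ratio of -0.01 and quartiles of -0.41 and 0.41. The 14 reference genes had a median of 0.04 and none passed the 2-fold rule. Among them Actb, which has an annotated transcript of 241 nt, was 8936 FPKM in f/f and 11908 in d/d, B2m 1346 and 1174, and Rplp0 782 and 819.

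The most strongly lower genes included 3 secreted products of uterine glands. The implantation serine protease Prss29 was 943 FPKM in f/f and 0.195 in d/d, and its neighbour Prss28 was 278 in f/f and listed at 0 in d/d. The protease inhibitor Spink1 was 578 FPKM in f/f and listed at 0 in d/d. Next came Cyp26a1, which degrades retinoic acid, at 181 and 0.380 FPKM, and the granzymes Gzmc and Gzmb, which are killer cell proteases, at 104 and 91.3 FPKM in f/f against 0 and 0.339 in d/d. The sulfotransferase Sult1d1 was 122 FPKM in f/f and 0.243 in d/d, and the tachykinin Tac2 was 67.0 in f/f and listed at 0 in d/d. Gpx3, the extracellular glutathione peroxidase, was the most abundant of these at 18908 FPKM in f/f and 423 in d/d, a 44.7-fold lower level. Ctla2a, an inhibitor of cysteine proteases, was 4005 FPKM in f/f and 84.8 in d/d. Cacnb4, at 76.2 and 0.109 FPKM, and Slc5a11, at 44.0 and 0.0249, complete the 12, and both have an annotated transcript under 250 nt, of 208 and 215 nt, for which FPKM is less certain. Prss28 and Prss29 lie side by side on chromosome 17, from 25308646 to 25311876 and from 25318654 to 25322684. Such related genes can exchange fragments in the authors' estimate.

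At the other end, Spink12 was listed at 0 in f/f and was 374 FPKM in d/d. Ltf, the lactoferrin gene and a textbook estrogen-induced gene of the uterine epithelium, was 3.71 FPKM in f/f and 647 in d/d, a 174-fold higher level, and it has an annotated transcript of 233 nt. The antimicrobial lipocalin Lcn2 was 65.6-fold higher, at 13.4 and 878 FPKM. Padi1, a peptidylarginine deiminase, was 85.3-fold higher, at 3.96 and 338 FPKM, and the sulfotransferase Chst8 was 169-fold higher, at 1.19 and 201 FPKM. The epithelial keratin Krt19 was 71.5-fold higher, at 4.87 and 348 FPKM. Small proline-rich genes filled 4 of the 12 places. Sprr2f was 10.4 FPKM in f/f and 649 in d/d, Sprr2a2 was 0.317 and 113, Sprr2d was 0.258 and 65.6, and Sprr1a was 0.390 and 75.3. These lie on chromosome 3 between 92215920 and 92485895, and the Sprr2 genes among them are near copies of one another, so that their single values are uncertain. Bcl2l15 at 0.135 and 81.6 FPKM, and Cfd, the fat-cell protease adipsin, at 0.0867 and 66.6 FPKM, complete the list.

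**Figure D1:**
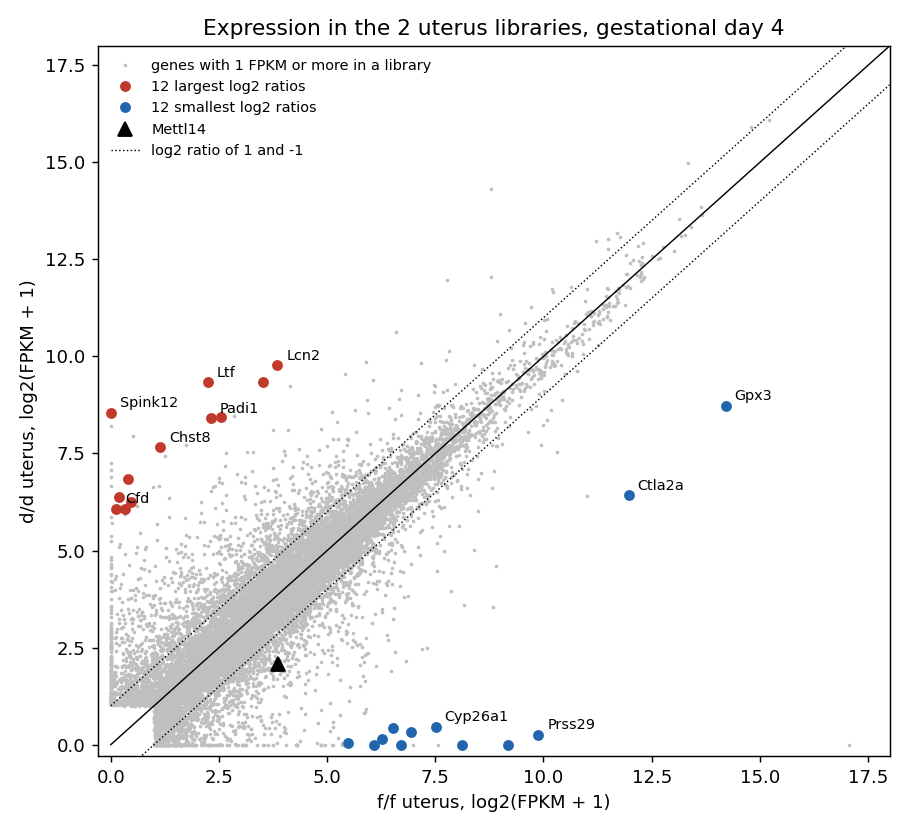
Each point is a gene with 1 FPKM or more in at least one library, with log2(FPKM + 1) in f/f on the x axis and in d/d on the y axis, the line of equality and dotted lines at log2 ratios of 1 and -1. Red and blue mark the 12 largest and 12 smallest log2 ratios by the naming rule, which leaves out gene models, and the triangle marks Mettl14 at 13.6 FPKM in f/f and 3.21 in d/d.

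Many genes known to respond to progesterone were lower in the d/d uterus. Of 30 measured, 19 were at least 2-fold lower, 1 was higher and 10 were neither, with a median log2 ratio of -1.99, lower than in any of the 10000 random lists. Of these 30 genes 14 also sit in another list, and the stroma, smooth muscle and endothelium lists had medians of -0.66, -0.66 and -0.82. Besides Cyp26a1, the activin-binding follistatin gene Fst was 57.6 FPKM in f/f and 0.800 in d/d, and Ihh, the epithelial Hedgehog ligand, was 13.7 and 0.435. Acod1, the enzyme that makes itaconate, was 21.4 and 0.739 FPKM. The transcription factor Zbtb16 was 12.3 and 0.717, and the calcitonin gene Calca was 7.18 in f/f and listed at 0 in d/d. The progesterone receptor itself, Pgr, was 43.7 FPKM in f/f and 57.4 in d/d (named here after its values were seen). The highest member was Sox17, an epithelial transcription factor, at 54.9 and 120 FPKM (also named after its values were seen).

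Estrogen-responsive genes showed the opposite direction. Of 33 measured, 23 were at least 2-fold higher in d/d, 4 were lower and 6 were neither, and the median log2 ratio of 3.43 exceeded that of every random list. The leading members were Ltf, Sprr2a2, Padi1, Lcn2, Sprr2f and Sprr2d, with the values given above. Without the Sprr2 and Padi families, which left 22 genes, the median was 2.24 and above every random list. The 4 lower members were Olfm1, Agr2, Aqp8 and Clca3a1, and the estrogen receptor Esr1 was 52.8 FPKM in f/f and 95.2 in d/d (Esr1, Olfm1, Agr2 and Clca3a1 named after their values were seen). Ltf and Lcn2 also stand in the neutrophil list. The general epithelial, fat-cell and macrophage lists were higher in the same library, with medians of 2.10, 2.57 and 0.81. Hormone levels of the animals were not analysed here.

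**Figure D2:**
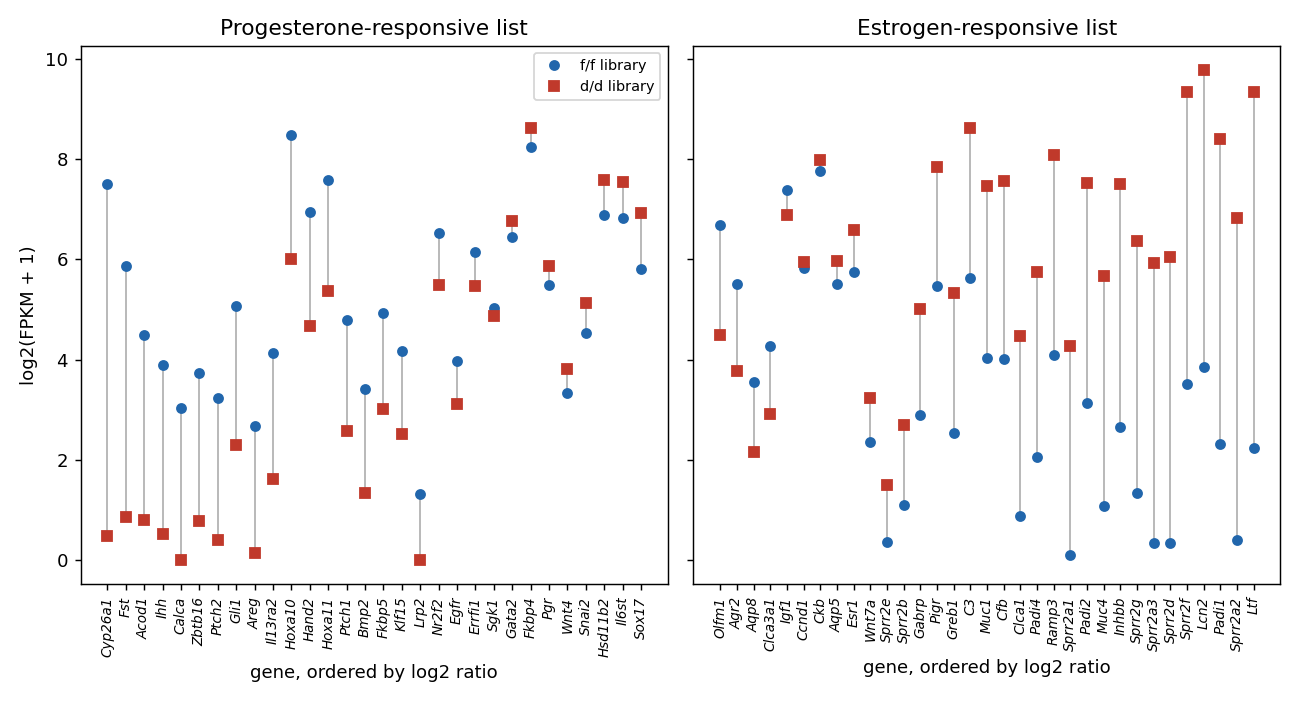
Measured genes of the progesterone-responsive list (left) and the estrogen-responsive list (right), ordered by log2 ratio, with log2(FPKM + 1) in the f/f library as circles and in the d/d library as squares, 1 library each. In the left panel 19 of 30 genes are at least 2-fold lower in d/d, from Cyp26a1 onward, and in the right panel 23 of 33 are at least 2-fold higher, up to Ltf.

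General epithelial and gland lists had medians of opposite sign. Of 20 general epithelial genes, 14 were at least 2-fold higher in d/d and 1 was lower (median log2 ratio 2.10, above every random list). Krt19, the epithelial transcription factor Elf3 at 6.19 and 355 FPKM, and the keratin Krt7 at 12.4 and 274 FPKM led. E-cadherin, Cdh1, was 20.8 and 154 FPKM and the keratin Krt8 was 27.2 and 193. In the gland list 7 of 13 genes were at least 2-fold lower and 2 were higher (median -1.52, lower than in any random list). Beside Prss29, Spink1 and Prss28, the lower genes included Prap1 at 456 and 10.7 FPKM and Wfdc3 at 15.0 and 0.242, whereas Fxyd4, a regulator of the sodium pump, was 3.27 FPKM in f/f and 74.5 in d/d. The other higher gland-list gene was Lif, at 0.976 and 12.7 FPKM. The gland transcription factors Foxa2 and Sox9 had log2 ratios of -0.42 and 0.38 (Foxa2 and Sox9 named after their values were seen). Of 6 measured genes of stratified squamous epithelium, 5 were higher (median 1.46, percentile 99.9). All 5 were under 1 FPKM in f/f, so they passed the filter through d/d alone. They were led by Sprr1a, with Krt13 listed at 0 in f/f and at 3.81 FPKM in d/d, Krt6a at 0.0253 and 1.98, Lor at 0.913 and 3.94, and Ivl at 0.123 and 1.69. The other measured gene, Krt10, did not differ, at 6.51 FPKM in f/f and 6.38 in d/d. The unmeasured ones of the 14 list genes stayed under 1 FPKM in both libraries. Krt5, Krt14, Krt4, Trp63 and Dsg3 were among them (these and Krt10 named after their values were seen). Without an expression filter the median of this list was 0.31. Of 18 ion and water transport genes, 8 were higher and 3 lower (median 0.48, percentile 99.1). The zinc transporter Slc39a2 was 0.163 and 15.2 FPKM, Clca1 was 0.833 and 21, and the chloride channel Cftr was 0.182 and 9.98, while Ano1 was 42.1 and 13.7 and the water channel Aqp8 was 10.8 and 3.46. Its sister Aqp3 was 0.239 and 2.17 FPKM. That list no longer stood apart without an expression filter or with one of 5 FPKM. The ciliated and oviduct list had 1 higher and 2 lower genes of 5 (median -0.47, percentile 19.5), with Ovgp1 at 13.0 and 0.352 FPKM, Cfap126 at 3.53 and 0.675, and Foxj1 at 0.130 and 1.46.

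Stromal, muscle and vessel lists had medians below 0. In the endometrial stroma list 6 of 15 genes were at least 2-fold lower and 1 was higher (median -0.66, lower than in any random list). The periostin gene Postn was 207 FPKM in f/f and 30.5 in d/d, and the stromal transcription factors Hoxa10, Hoxa11 and Hand2 were 357 and 63.7, 193 and 40.3, and 122 and 24.3. The growth factor receptor Pdgfra was 92.5 and 25 FPKM, and vimentin, Vim, was 1081 and 328. Hoxa10, Hoxa11 and Hand2 are members of the progesterone list as well. The matrix genes Dcn, Lum, Col1a1 and Col1a2 had log2 ratios of -0.17, -0.16, -0.29 and -0.13, and the higher gene was Col6a3, at 1.14 (these 5 named after their values were seen). Of 14 smooth muscle genes, 4 were lower and none was higher (median -0.66, lower than in any random list), namely Des at 465 and 131 FPKM, Synpo2 at 89.6 and 35.9, Casq2 at 3.05 and 0.913, and Actg2 at 837 and 401. By their mean the smooth muscle genes no longer stood apart. All 14 endothelial genes had ratios below 0 (median -0.82, lower than in any random list) and 4 passed the 2-fold rule. These were Cdh5 at 72.5 and 29.8 FPKM, the angiopoietin receptor Tek at 20.3 and 8.18, Emcn at 54.5 and 24.0, and Esam at 68.2 and 31.6.

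Wnt and Hedgehog signalling genes were largely lower, 14 of 24 at least 2-fold and 1 higher (median -1.42, lower than in any random list). Wnt11, a Wnt ligand, was 34.2 FPKM in f/f and 0.374 in d/d, and the Wnt-pathway transcription factor Lef1 was 44.6 and 1.19. The secreted Wnt antagonists Sfrp2 and Sfrp4 were 94.2 and 4.26, and 109 and 13.0. Lgr5, an R-spondin receptor, was 7.45 in f/f and listed at 0 in d/d. In the list of stromal FGF and epithelial growth genes, 3 of 16 were higher and 5 lower (median 0.21, percentile 89.5). Igfbp3, which binds insulin-like growth factors, was 480 and 23.2 FPKM. The growth factors Hgf, Areg and Fgf9 were 18.7 and 2.36, 5.39 and 0.0935, and 4.02 and 0.130, and Fgf1 was 3.74 and 18.7. The receptor Fgfr3 was 3.43 and 0.738. Extracellular matrix genes went both ways, 9 of 38 higher and 4 lower (median -0.16, percentile 5.72). Lower were the matrix protease Mmp3 at 13.0 and 0.514 FPKM, Col14a1 at 64.7 and 7.78, and Col15a1 at 137 and 33.1. The laminin gene Lama1 was higher at 0.721 and 4.14, as was Fbln2 at 52.2 and 149.

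All 28 cell cycle genes had log2 ratios below 0, and 5 passed the 2-fold rule (median -0.64, lower than in any random list). The ribonucleotide reductase subunit Rrm2 was 68.9 FPKM in f/f and 16.7 in d/d, the cyclins Ccne2 and Ccna2 were 19.7 and 6.25, and 52.6 and 25.4, Top2a was 110 and 46.1, and Cdc20 was 59.7 and 29.0. In the p53 and apoptosis list 2 of 18 genes were higher and none was lower (median 0.46, percentile 99.8). The cell cycle inhibitor Cdkn1a was 14.9 and 74.7 FPKM, and the stress cytokine Gdf15 was 0.246 and 28.8.

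Genes of implantation and decidualization went both ways, with 8 of 30 higher and 7 lower (median -0.12, percentile 16.4). Ihh was lower, while Lif, the cytokine needed for implantation in mice, was 0.976 FPKM in f/f and 12.7 in d/d. The homeobox gene Msx2 was 0.373 and 12.7, Dlx5 was 10.2 and 75.1, the alkaline phosphatase gene Alpl was 9.26 and 59.5, and Cdh1 was higher as given above.

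**Figure D3:**
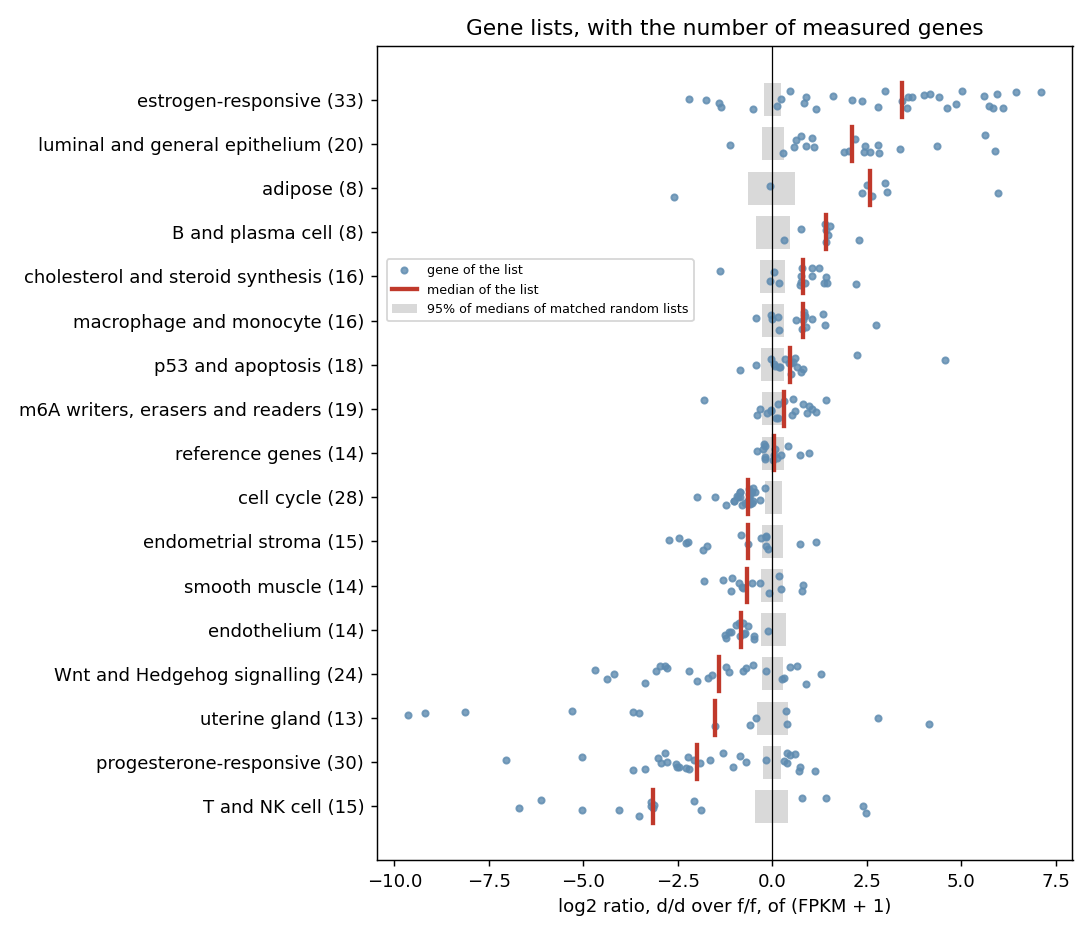
Log2 ratio of d/d over f/f on (FPKM + 1) for the measured genes (points) of 17 of the 40 lists, with each list's median (red line) and the range that holds 95% of medians of matched random lists (grey). Medians run from 3.43 for the estrogen-responsive list to -3.15 for the T and NK cell list, and the reference genes lie at 0.04.

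Leukocyte lists went both ways. In the T and NK cell list 11 of 15 genes were at least 2-fold lower and 3 were higher (median -3.15, lower than in any random list). The lower ones were genes of natural killer cells and cytotoxic granules. Beside Gzmc and Gzmb, the chemokine Xcl1 was 56.8 FPKM in f/f and 0.755 in d/d, the granule protein Nkg7 was 56.3 and 2.42, the activating receptor Ncr1 was 14.9 and 0.368, and perforin, Prf1, was 11.6 and 0.355. The 3 higher genes belong to T cells, namely Cd3e at 1.39 and 11.6 FPKM, Cd3g at 5.22 and 33.7, and Cd4 at 0.657 and 3.41 (named after their values were seen). Macrophage and monocyte genes were higher in 4 of 16 cases and lower in none (median 0.81, above every random list). Among them the lipopolysaccharide co-receptor Cd14 was 12.9 and 91.6 FPKM, the lysozyme Lyz2 was 334 and 886, Adgre1 was 17.6 and 46.6, and Cd68 was 24.2 and 50.8. Of 8 B and plasma cell genes, 6 were higher and none was lower (median 1.42, percentile 99.99). The immunoglobulin genes Igkc, Igha and Iglc2 were 1198 and 3217 FPKM, 589 and 1647, and 12.4 and 64.5, Jchain was 142 and 371, Mzb1 was 3.75 and 11.7, and Cd79b was 1.74 and 6.87.

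The neutrophil list had 4 higher genes of 9 and none lower (median 0.72, percentile 99.3), but without the genes shared with other lists, Ltf and Lcn2 among them, its median was 0.51 and no longer stood apart. The neutrophil genes Ly6g and S100a9 were listed at 0 in f/f and at 9.52 FPKM in d/d, and at 2.67 and 9.51. No gene of 11 in the MHC class II and dendritic cell list passed the 2-fold rule (median 0.12, percentile 77.5), with Cd74 at 396 and 562 FPKM, H2-Eb1 at 208 and 318, and H2-Aa at 202 and 318. Of 10 mast cell and eosinophil genes, 4 were lower (median -0.14, percentile 45.3), all mast cell proteases below 5 FPKM. These were Mcpt4 at 2.59 and 0.159, Cpa3 at 2.56 and 0.335, Tpsb2 at 3.25 and 0.825, and Cma1 at 2.39 and 0.505.

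The list of inflammatory cytokines, chemokines and related enzymes had 3 higher and 3 lower genes of 22 (median -0.20, percentile 23.7). The eosinophil chemokine Ccl11 was 8.58 FPKM in f/f and 131 in d/d, Il1a was 1.15 and 3.66, and Il17a was 0.0572 and 1.47. Lower were Il33 at 8.50 and 2.26, Cxcl10 at 12.8 and 4.85, and the prostaglandin synthase Ptgs2 at 1.29 and 0.103. Interferon-stimulated genes had 2 higher and 4 lower of 28 (median -0.25, percentile 1.68). Lower beside Cxcl10 were the guanylate-binding proteins Gbp3 at 66.6 and 23.3 FPKM, Gbp2 at 29.5 and 13.3, and Gbp5 at 6.30 and 2.28, while Mx1 was 5.55 and 13.9 and Rtp4 was 77.0 and 162. That list did not stand apart under 5 other settings. Immediate early genes had 2 higher and 2 lower of 17 (median -0.42, percentile 0.66) and did not stand apart under 5 other settings. Myc was 77.8 and 20.6 FPKM and Fosl1 was 2.32 in f/f and listed at 0 in d/d, whereas Jund was 177 and 542 and Fos was 8.72 and 22.8.

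Cholesterol and steroid synthesis genes were higher in 7 of 16 cases and lower in 1 (median 0.82, percentile 99.98). The steroid dehydrogenases Hsd17b2 and Hsd17b11 were 1.19 FPKM in f/f and 4.85 in d/d, and 53.5 and 126, whereas the steroid reductase Srd5a1 was 11.1 and 3.61. In the unfolded protein and integrated stress response list 1 of 18 genes passed the rule, the serine synthesis gene Phgdh at 15.0 and 2.75 FPKM (median 0.01, percentile 55.8).

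Markers of tissues that could be carried over at dissection also differed. Of 8 adipose genes, 6 were higher in d/d and 1 was lower (median 2.57, above every random list). Beside Cfd, the fatty acid carrier Fabp4 was 2.67 and 28.9 FPKM, Car3 was 0.412 and 7.77, and Retn and Cidec were listed at 0 in f/f and at 6.91 and 4.69 FPKM in d/d, whereas Pck1 was 5.73 and 0.114. Of 11 skeletal muscle genes 5 were measured, and all 5 were lower (median -1.25, percentile 0.24). Tnni2 was 92.7 and 10.4 FPKM, Acta1 115 and 13.2, Tnnt3 7.51 and 2.79, Mylpf 5.31 and 2.03, and Ckm 1.66 and 0.119. The unmeasured ones stayed under 1 FPKM in both libraries. Whether these transcripts came from carried-over muscle or from the uterus itself was not tested. None of the other lists for carried-over tissue stood apart. The mesothelial list (6 genes, median 0.17, percentile 73.8) held Krt19, with Wt1 at 84.3 and 17.5 FPKM and Upk3b at 1.87 and 0.332. Among 5 ovarian genes (median -0.65, percentile 20.1), Cyp11a1 was 2.32 and listed at 0, Star was 3.92 and 0.982, and Zp1 was 0.0301 and 1.57. Of 4 blastocyst genes (median -1.07, percentile 3.67), Eomes, also a member of the T and NK cell list, was 3.42 and 0.0527. Dppa5a was 1.38 and listed at 0, and Dppa3 was listed at 0 and 1.09. No Y-linked gene reached 1 FPKM. Red blood cell genes (5 genes, median -0.21, percentile 22.5) included Hbb-bs at 274 and 241 FPKM, Hba-a2 at 140 and 109, and Hba-a1 at 92.0 and 79.6. In the nerve and glia list (5 genes, median -0.38, percentile 35.7) Prph was 2.67 and listed at 0, and Mbp was 2.81 and 9.40.

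The lists that track RNA handling lay within the range of random lists in the main setting, but not in every setting. Nuclear-retained RNAs stood below it with no filter (percentile 1.68) and after the GC correction (2.49). Mitochondrially encoded genes stood above it after the GC correction (98.3). The 13 mitochondrially encoded genes had a median of 0.21 (percentile 95.2), and mt-Atp8, a gene of 204 nt, was the 1 past the rule at 28281 and 61587 FPKM. None of 12 replication-dependent histone genes passed (median -0.24, percentile 35.2), with H2bc4 at 105 and 90.5 FPKM, H2ac11 at 9.27 and 6.03, and H2ac8 at 2.85 and 3.89. Of 6 nuclear-retained RNAs, 2 were lower (median -0.46, percentile 2.63), Neat1 at 33.7 and 11.9 FPKM and Meg3 at 12.5 and 5.17. In all, 10 of the 39 lists stood above and 11 below the range of random lists.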

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

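The alternatives with protein-coding genes alone, without short transcripts, with GC correction and without shared or family members were chosen after the data were seen. No paired analysis was possible because there is 1 library per genotype, and for the same reason no replicate could be left out. The counts of 1652 higher and 1346 lower genes became 3063 and 2888 under a 1.5-fold rule and 483 and 311 under a 4-fold rule, by construction of the rule. Under the other settings they stayed within 1.5 times, and the absence of a filter could not move them because a gene under 1 FPKM in both libraries cannot reach 2-fold with the pseudocount of 1. The log2 ratio of Mettl14 ranged from -2.05 to -1.73. The progesterone list ranged from -2.29 to -1.48, the estrogen list from 2.24 to 3.51, and both stood apart under all 14 settings. Removing the Sprr2 and Padi families took no gene from the progesterone list. Lists whose median moved most while standing apart throughout were squamous epithelium (0.31 to 3.53), adipose (1.67 to 4.05), T and NK cell (-4.34 to -2.34), skeletal muscle (-3.00 to -1.11) and uterine gland (-2.64 to -1.05). Of 21 lists that stood apart, 5 lost that under some setting. Immediate early genes did so rescaled to TPM (-0.29), with no filter (-0.29), at 5 FPKM (-0.23), by their mean (-0.14) and without shared genes (-0.29). Interferon genes did so against unmatched lists (-0.25), by their mean (-0.16), among protein-coding genes (-0.22), after GC correction (-0.22) and without shared genes (-0.22). Ion and water transport did so with no filter (0.089) and at 5 FPKM (0.46), smooth muscle by its mean (-0.48), and neutrophil genes without shared genes (0.51). The cause was not tested. Another 10 list values came to stand apart, among the m6A, ciliated, nuclear-retained, dendritic cell, extracellular matrix, blastocyst and mitochondrial lists. No list or named gene past its threshold reversed. Named genes and Mettl14 were run under 5 settings only, and the GC correction was not among them. These were a pseudocount of 0.1, TPM, centring, the total without the 50 most abundant genes and the highest row per symbol. The TPM, centring and reduced-total settings shift the libraries against each other by -0.0046, -0.0031 and -0.020 on the log2 scale. Such shifts could move few genes. Rescaling to TPM also made the values of both libraries smaller while the pseudocount and the filter stayed at 1. This pulls the ratios of genes at low FPKM toward 0. Across 187 named genes per setting, 928 values kept their side of the 2-fold rule. Foxj1, Casq2, Ptgs2, Upk3b, Dppa3 and Mylpf came under it when rescaled to TPM, and Rbm15b passed it at a pseudocount of 0.1 (1.01). At 1 FPKM a 2 kb transcript rests on about 35.4 fragments in f/f, so genes near that level carry wide counting error, and variation between animals is unknown at any depth.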

Other observations

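The gene families described first and the tests of swapped labels, scaling, epithelial share, animal state, fat and DRACH motifs were chosen after the result was seen, while the short-transcript and 3' UTR tests were set down first. Families built around genes already seen to differ have no percentile here, since that choice would set it. All 10 measured homeobox genes of the A and D clusters had log2 ratios below 0, and 4 were at least 2-fold lower in d/d (median -0.79). Beyond Hoxa10 and Hoxa11 these were Hoxd11, at 79.6 FPKM in f/f and 13.5 in d/d, and Hoxd4, at 12 and 2.61. Of 9 neuropeptide and monoamine genes, 7 were at least 2-fold lower and none was higher (median -3.71). Beside Tac2 and Calca, the opioid precursor Penk was 146 and 4.46 FPKM, Npy was 33.6 and listed at 0, the noradrenaline transporter Slc6a2 was 39.7 and 0.0365, and the monoamine oxidases Maoa and Maob were 26.4 and 10.5, and 83.8 and 5.50. IGF-binding proteins had 2 lower genes of 6 (median -0.80), Igfbp3 and Igfbp4, the latter at 795 and 267 FPKM.

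Retinoid genes went both ways (17 measured, 3 higher, 4 lower, median 0.06). Cyp26a1, which degrades retinoic acid, the retinol importer Stra6 at 47.2 and 5.51 FPKM, Crabp1 at 7.38 and 0.339, and Rbp4 at 21.3 and 3.94 were lower. Crabp2 at 0.157 and 35.2 FPKM, Aldh1a1 at 11.8 and 48.7, and Rdh10 at 25 and 63.9 were higher. Of 11 mucins 3 were measured and all 3 were higher, Muc1 at 15.4 and 176 FPKM, Muc4 at 1.09 and 50.2, and Muc20 at 0.589 and 42.7. Muc1 and Muc4 are members of the estrogen list as well, and Muc20 passed the filter through d/d alone. Selenoproteins had 6 higher and 4 lower genes of 24 (median 0.09), with very large opposite differences at 2 glutathione peroxidases. Gpx3 was 18908 and 423 FPKM, and Gpx4 was 440 and 20289. Txnrd1 was 217 and 4029 FPKM. The values of Gpx4 and Txnrd1 rest on the authors' estimate per transcript and were not checked against reads here, so their size is uncertain. Selenoo was 4.33 and 67.1, Dio2 was 17.9 and 93.2, and Dio3 was 58.8 and 4.03.

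A broad pattern was that estrogen-list genes were higher and progesterone-list genes lower in d/d. A swap of the 2 labels is argued against by Mettl14, whose log2 ratio was -1.80. A scaling difference is argued against too, since 1 factor for all genes would shift both lists alike, and their medians lay 5.43 apart on the log2 scale. A larger epithelial share in d/d is neither shown nor excluded, with log2 ratio quartiles of 0.86 and 2.79 for the general epithelial list, -5.29 and 0.36 for the gland list (median -1.52), -2.04 and -0.16 for stroma, where Dcn and Lum were near 0 and Col6a3 was higher, -1.02 and 0.10 for smooth muscle and -1.06 and -0.67 for endothelium. Whether the pattern may come from the stage or hormonal state of the one d/d sample rather than from its genotype cannot be told apart, because there are 0 further d/d libraries, and an effect of the genotype on these genes stays open as well.

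Several of the highest FPKM values belonged to very short gene models. The pseudogene Gm13392, of 150 nt, was 136641 FPKM in f/f and listed at 0 in d/d, and 12 of the 25 highest genes had an annotated transcript under 250 nt, against 4.29% of all 16263 genes. Among genes at 100 FPKM or more, 46 of 123 with such a transcript passed the 2-fold rule (37.4%, exact Clopper-Pearson 95% interval 28.8 to 46.6%, counting error only), against 254 of 1553 others (16.4%, 14.5 to 18.3%), a ratio of 2.29. The length correction of the FPKM estimate could inflate both levels and ratios of such models in this way. Several of them are pseudogenes, such as Gm13392 and Gm14303, so fragments shared between gene copies could do so as well. The test cannot tell these sources of error apart. Gpx4, with a shortest transcript of 280 nt, falls outside the class under 250 nt, so its difference is not accounted for by this test. No biological explanation was tested. Named genes past the 2-fold rule that also have an annotated transcript under 250 nt include Alpl, Mylpf, Krt13, Esam and Fbln2. Their shortest transcripts are 151, 165, 207, 216 and 223 nt, so their FPKM is less certain too.

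Most measured genes of the adipose list, 6 of 8, were at least 2-fold higher in d/d. Of 7 fat-cell genes picked from it (Adipoq, Plin1, Cfd, Car3, Lep, Retn and Cidec), 7 had more FPKM in d/d, but 5 had passed the 2-fold rule when they were picked, so this count decides nothing, and Ucp1, left out of the 7, was 0.0748 and 0. The most abundant list genes in d/d were Cfd at 66.6 FPKM, Fabp4 at 28.9, Lipe at 10.9, Car3 at 7.77, Retn at 6.91 and Adipoq at 5.26. In f/f 3 of the 12 list genes reached 1 FPKM, namely Fabp4, Lipe and Pck1, and of these Lipe was 11.5 and 10.9 FPKM and Pck1 5.73 and 0.114. Fat carried over with the d/d uterus, which no sort or gate would have removed, and an effect of the genotype on these genes cannot be told apart with 1 library each.

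A hypothesis was tested that loss of m6A raises the level of transcripts likely to carry it. If so, log2 ratios would increase with 3' UTR length, where m6A is dense, or with the density of DRACH motifs, its sequence context. Across 13715 genes Spearman's rho with 3' UTR length was 0.046, and across 13754 genes rho with DRACH motifs per kb was -0.024, both under the bound of 0.1 set for the hypothesis. Log2 ratios thus had little relation to either feature in these libraries. Genes are not independent replicates, and no m6A measurement was used here. Both features only stand in for m6A, and the many other differences between the libraries could hide a weak relation. The test therefore cannot exclude an effect of m6A loss on transcript levels, whether broad or on a smaller set.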
